A study of Danio rerio with 8 samples.

How the data were processed

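Gene expression was measured by RNA sequencing in 8 libraries, 4 of animal ectoderm and 4 of lateral ectoderm of zebrafish embryos at 7.5 hours post fertilization. Per the labels' protocols, embryos received 125 pg of PAmCherry1 mRNA at the 1-cell stage, the region was photoactivated from 6 hours onward over about 90 minutes, and 5000 fluorescent cells per library were sorted into lysis buffer. Libraries were made by the SMART-Seq v3 protocol and read in pairs of 150 bases. Whether molecular identifiers were read or counted is not given in the sources used here.

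Per the submitters' processing notes, FastQC, Trimmomatic, Salmon and DESeq2 were used with the genome build GRCz11. Versions, options and the annotation release are not given in the sources used here. The deposited values are estimated counts per transcript (not normalised, 1 file per library, replicates not pooled) and the authors' TPM values, which divide by an effective transcript length that differs between libraries. Salmon divides reads that fit several transcripts, so that a transcript's estimated count can be a fraction. Of the tested transcripts, 32.3% had whole-number estimates, equal to the nearest integer at the deposited precision, in all 8 libraries. The files hold no resampled estimates, so the uncertainty of this division is not in the tests, and transcripts of one gene or of similar genes are uncertain for that reason.

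The plan, written before the data were examined, was to sum transcripts to genes, to name genes by a fixed rule and to test 27 fixed gene lists. The files give Ensembl transcript identifiers, and 0 of the 57192 identifiers occur in the tables of gene names used here. The planned test was therefore run per transcript, and the gene lists were not tested. The rule for named genes asked for the largest changes each way among transcripts past the threshold, with a mean log2 CPM of at least 3 and complete separation of the 2 groups, for genes with a symbol. Without symbols, the first 2 identifiers in each direction are given, and other transcripts are described without an identifier. Those described as the most abundant or as having the smallest adjusted p were chosen after their values were seen.

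Estimated counts were rounded to whole numbers and filtered with filterByExpr (minimum count 10, minimum total 15). They were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with the region as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are lateral over animal. Fitted fold changes use a prior count of 0.125, and standard errors are the fold change over the square root of the F statistic. CPM values are scaled by TMM over the tested transcripts, which held 98.1% to 98.5% of the reads of each library. Library similarity and principal components used log2 CPM with a prior count of 2. Library measures were compared by exact two-sided permutation tests over all 70 assignments, adjusted over 10 measures. Every pair of libraries differed by more than sampling noise, with chi-square values per degree of freedom from 7.86 to 20.8, so no pair was merged as repeat copies of 1 library. This does not tell whether libraries share a pool of cells.

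The test was tried on simulated counts drawn from the real means, depths and dispersions, with 200 transcripts changed by 2-fold to 16-fold. Of all simulated transcripts, changed or not, 9007 passed the filter and were tested. Of 129 calls 7 were false, and 0 calls were made with no change. Alternatives comprised DESeq2 1.42.0, limma voom 3.58.1, other scalings and filters, robust dispersions, effective length offsets, 1 surrogate variable (sva 3.50.0), the replicate number as a block, stricter thresholds and leaving out each library. Intervals and floors cover counting error only.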

Results

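RNA was sequenced from cells of 2 ectoderm regions of the early zebrafish gastrula, taken at 7.5 hours post fertilization. The ectoderm is the outer germ layer, which gives rise to the epidermis and the nervous system. One region lay at the animal pole, the top of the embryo, and the other on the side of the embryo. Each region gave 4 libraries, each made from 5000 sorted cells. The embryos carried the photoactivatable red fluorescent protein PAmCherry1, and a volume of 444 by 220 by 58.5 µm in the chosen region had been switched on with a 405 nm laser so that its cells could be sorted. Total estimated reads per library ran from 2439220 to 3807571 in animal ectoderm and from 1720408 to 2810129 in lateral ectoderm. Of 57192 listed transcripts, 30850 had at least 1 read and 9694 were abundant enough to test. Features are single Ensembl transcripts, because no table used here pairs these transcript identifiers with genes, so gene names and positions are not given and no gene group was tested. Replicates are separate samples per the labels, and since nothing says that they came from separate clutches, p-values measure the spread between these samples.

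The comparison of the regions asked which transcripts differ between the ectoderm at the animal pole and the lateral ectoderm, the study's stated interest being the expression differences behind the differing material properties of these tissues. A small set of transcripts differed between the regions. In total 29 of 9694 transcripts passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 20 were higher in lateral and 9 higher in animal ectoderm. An even division was not excluded (exact two-sided binomial p = 0.0614), in a test that treats transcripts as independent, which they are not. In all 29, the 4 libraries of one region lay above the 4 libraries of the other. The same complete separation held for 411 of the tested transcripts, or 4.24%, where chance gives 2.86%. With DESeq2, the tool named in the submitters' processing notes, 90 of 12790 transcripts passed, among them all 29. The filter there differed from that of the edgeR test, so the counts do not rest on the same transcripts. With limma voom 17 passed, 9 higher in lateral and 8 higher in animal ectoderm. Without animal replicate 3 the count was 18. Without lateral replicates 1 and 4, which stand apart from the other libraries, it was 14, of which 8 were among the 29. With the replicate number as a block the count was 9, and with no filter on low counts it was 290 of 30850 tested.

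**Figure D1:**
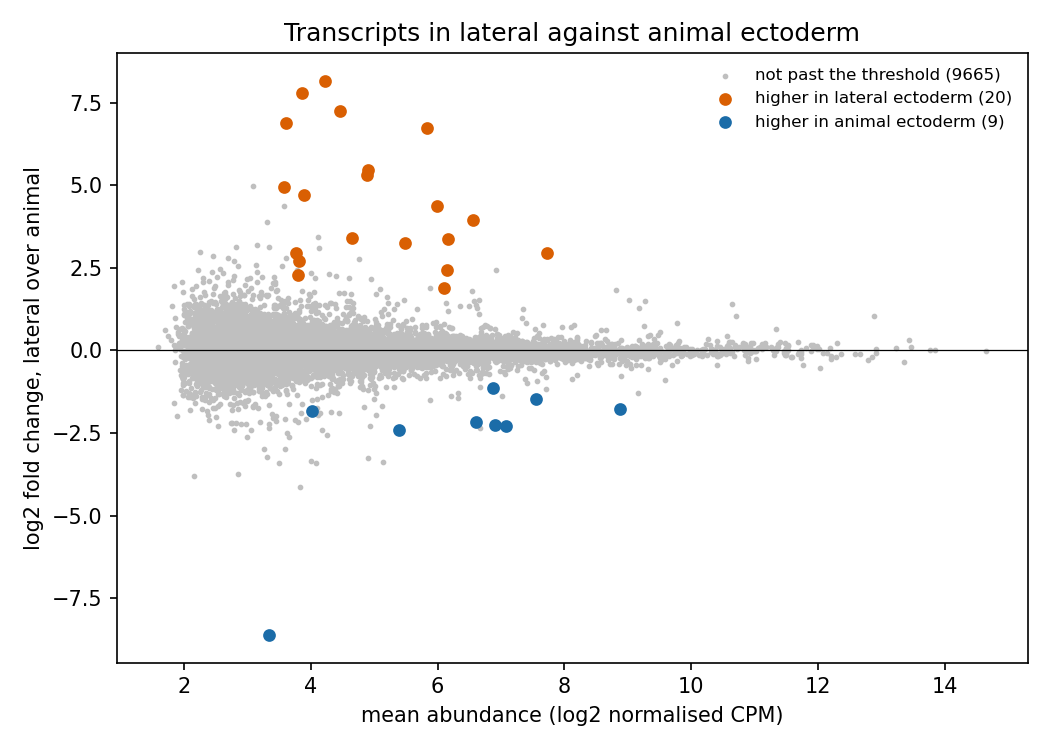
Each point is 1 of the 9694 tested transcripts, with its mean abundance as log2 of normalised CPM (counts scaled to the size of the library) on the x axis and its log2 fold change, lateral over animal, on the y axis. Orange points (20) were higher in lateral ectoderm, blue points (9) were higher in animal ectoderm, and grey points did not pass the threshold.

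The 20 transcripts higher in lateral ectoderm had a median log2 fold change of 4.15, with a range from 1.88 to 8.16. As log2 ratios of pooled normalised counts, with group totals raised to at least 3 counts, the median was 4.09. Only 4 of the 20 had 3 counts or fewer in animal ectoderm, and their changes were the largest. The floor could therefore not move the median, and the shift comes from the other estimate. Of the 20, 14 exceeded an 8-fold difference and 9 had a mean below 2 normalised CPM in animal ectoderm. Their median abundance was 3.33 CPM in animal and 51.1 CPM in lateral ectoderm. Together they made up 159 CPM in animal ectoderm and 1631 CPM in lateral ectoderm. The smallest adjusted p belonged to a transcript of 4558 nucleotides, at 8.35 ± 1.45 CPM (SD, n = 4) in animal and 80.1 ± 12.19 CPM (SD, n = 4) in lateral ectoderm. Its log2 fold change was 3.25 with a standard error of 0.22 and an adjusted p of 0.000215 in edgeR. The most abundant of the 20 stood at 48.5 ± 32.6 CPM (SD, n = 4) in animal and 376 ± 43.9 CPM (SD, n = 4) in lateral ectoderm.

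Of the 9 transcripts higher in animal ectoderm, 7 were above 10 CPM in lateral ectoderm as well and 1 had no reads there. Their median fitted log2 fold change was -2.15. As log2 ratios of pooled normalised counts, with group totals raised to at least 3 counts, the median was -2.19. The floor applied only to the transcript with no reads, so the shift comes from the other estimate and not from the floor. Their median abundance was 159 CPM in animal and 41.3 CPM in lateral ectoderm. The most abundant of them stood at 725 ± 100.05 CPM (SD, n = 4) in animal and 210.4 ± 57.7 CPM (SD, n = 4) in lateral ectoderm, a log2 fold change of -1.78 with a standard error of 0.19 and an adjusted p of 0.00331 in edgeR. The number of transcripts called higher in animal ectoderm was 4, 4 and 3 without animal replicates 1, 3 and 4 respectively. This number was 1 with the replicate number as a block and 2 at an adjusted p of 0.01. In the other direction it was 33 with DESeq2 and 113 with no filter on low counts, both of which tested more transcripts.

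**Figure D2:**
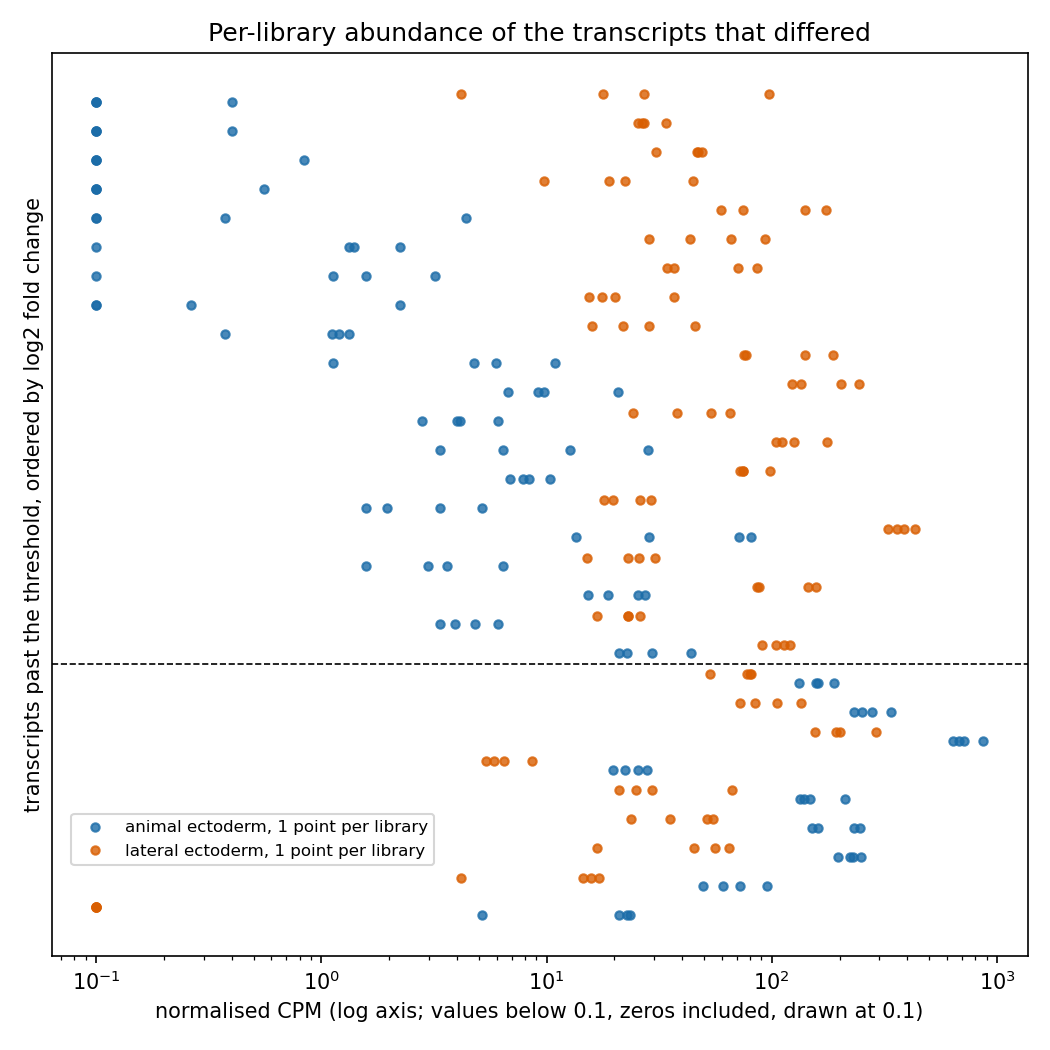
Each row is 1 of the 29 transcripts past the threshold, ordered by log2 fold change, and each point is 1 library on a log axis of normalised CPM, with values below 0.1 drawn at 0.1. The 20 rows above the dashed line were higher in lateral ectoderm (orange) and the 9 rows below it were higher in animal ectoderm (blue), with no overlap between the regions in any row.

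The transcripts with the largest changes were those close to absent in one region. ENSDART00000057053.6 had 1 read over the 4 animal libraries and 246 reads over the 4 lateral libraries. It stood at 28.2 ± 3.86 CPM (SD, n = 4) in lateral ectoderm. The ratio of its pooled normalised counts was 349, with an exact 95% interval of 62.0 to 13835 that covers counting error only. Its adjusted p was 0.000809 in edgeR. Its fitted log2 fold change was 7.79, and 9.25 without animal replicate 2, which held the only animal read, so that this value depends on the prior count. ENSDART00000136415.3 also had 1 read in animal ectoderm, against 310 in lateral ectoderm, a ratio of 439.6 with an interval of 78.3 to 17419. Its lateral libraries were unequal, at 4.19, 27.0, 97.1 and 17.9 CPM in replicates 1 to 4, and its adjusted p was 0.0225 in edgeR. Its fitted log2 fold change was 8.16, against 7.01 without lateral replicate 3, which held 195 of the 310 reads, and 9.62 without animal replicate 2, which held its only animal read. Its call ended when any 1 of the 4 animal libraries or lateral replicate 2 was left out. The call also ended with limma voom, with robust dispersions, with limma on TPM and at an adjusted p of 0.01.

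In the other direction, ENSDART00000105286.5 had 237 reads in animal ectoderm and 0 in lateral ectoderm. With the lateral group set to a floor of 3 counts, its ratio of animal over lateral was 55.7. This ratio is not a minimum. The exact interval, of the kind given above, starts lower, at 45.0, and covers counting error only. ENSDART00000105286.5 stood at 18.1 ± 8.65 CPM (SD, n = 4) in animal ectoderm, with an adjusted p of 0.0225 in edgeR. Its reads were not whole numbers, so they had been divided between it and similar transcripts. Its call ended when any 1 library other than animal replicate 2 was left out and without lateral replicates 1 and 4 together. The call also ended with limma voom, with limma on TPM, at an adjusted p of 0.01 and with the replicate number as a block (adjusted p 0.223 in edgeR). ENSDART00000126097.4 stood at 69.3 ± 19.5 CPM (SD, n = 4) in animal and 12.9 ± 5.93 CPM (SD, n = 4) in lateral ectoderm. Its log2 fold change was -2.40 with a standard error of 0.37 and an adjusted p of 0.0238 in edgeR. Its reads had been divided too. Its call ended without animal replicate 2, 3 or 4, without lateral replicate 1, 2 or 3, and without lateral replicates 1 and 4 together. The call also ended in a test against a 1.5-fold change, at an adjusted p of 0.01 and with the replicate number as a block (adjusted p 0.267 in edgeR).

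None of the 100 most abundant tested transcripts, each at 1727 CPM or more, passed in edgeR. Of these, 7 had an unadjusted p below 0.05, DESeq2 called 1, edgeR with no filter on low counts called 3, and limma voom called 0. Their median absolute log2 fold change was 0.11, beside a median standard error of 0.13, and the largest was 1.05. Over all tested transcripts, 499 had an unadjusted p below 0.05, where 484.7 are expected with no difference anywhere. The median standard error was 0.38 on the log2 scale, with medians of 0.64 among tested transcripts at 3.02 to 8.55 CPM and 0.19 among those above 51.3 CPM. In simulated libraries of the same depth and estimated dispersions, 200 transcripts were changed, and 9007 transcripts in all, changed or not, were tested. The test recovered 9.09% of 2-fold, 57.4% of 4-fold and 89.6% of 8-fold changes over all abundances together. These rates come from a single simulated draw and count only changed transcripts that passed the filter. The simulation gave 129 calls against 29 in the real data, and more calls ease the Benjamini-Hochberg threshold. Each simulated transcript was also drawn independently, without deviations that a library shares over many transcripts. Recovery in the real comparison can therefore be lower. Of the 107 transcripts with a fitted difference above 4-fold, 83 did not pass.

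Transcripts found in a single region were few. With at least 10 reads in each library of one region and at most 3 reads in all libraries of the other, 4 transcripts were found in lateral ectoderm, all of which passed the edgeR test, and 1 in animal ectoderm. Among the 68 other assignments of the 8 libraries to groups of 4, 5 gave 4 or more such transcripts, with a highest number of 5, and 48 gave at least 1.

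Pearson correlations of log2 CPM between libraries, computed across transcripts, which are not independent replicates, averaged 0.890 among animal libraries, 0.852 among lateral libraries and 0.863 between the regions. The difference of 0.0372 between the animal and the lateral mean did not pass an exact permutation test (p = 0.171), and it was 0.0227 without lateral replicate 1. The real grouping still gave the largest excess of within-region over between-region correlation, 0.00793, among the 35 splits of the libraries into 4 and 4. A share of 1 in 35 is the smallest this comparison can give. Lateral libraries correlated less with one another than with animal libraries, so the excess came from the animal group. The first principal component held 21.3% of the variance and set lateral replicates 1 and 4 at opposite ends, with the other 6 libraries between them. On component 2 the animal libraries lay above the lateral ones, from 12.45 to 32.7 against -60.6 to 9.485. Animal libraries were deeper on average, at 3191230 ± 674897 reads (SD, n = 4) against 2254200 ± 464184 reads (SD, n = 4), with an exact two-sided permutation p of 0.0857 (adjusted p 0.286). Of 10 library measures compared, the smallest exact permutation p was 0.0286, for the share of reads in transcripts with divided reads, at 69.7% ± 1.17 in animal and 67.0% ± 0.94 in lateral ectoderm (SD, n = 4). Its adjusted value was 0.286, and 0.0286 is the smallest p that this design allows.

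**Figure D3:**
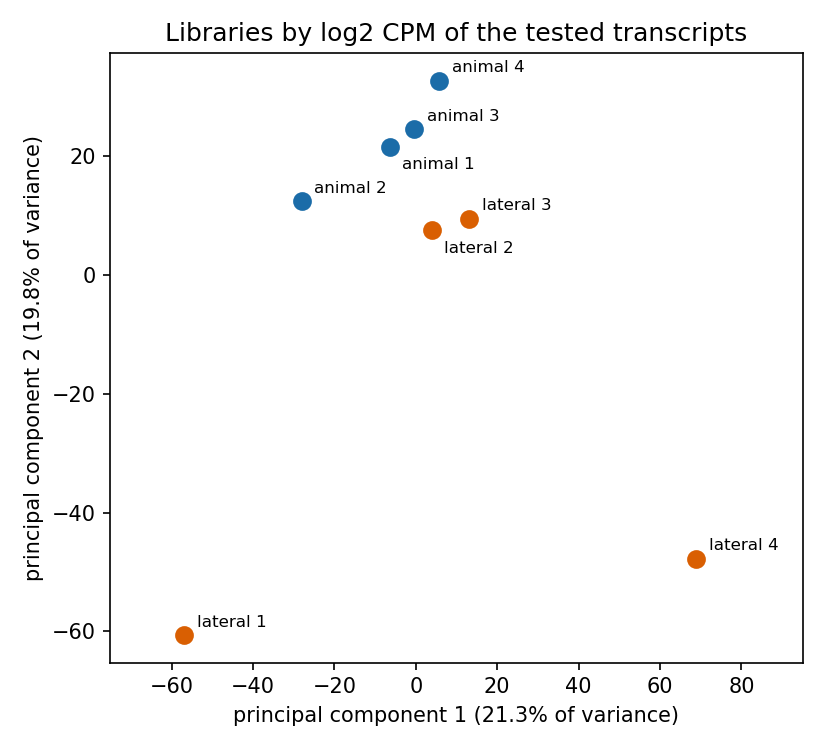
Principal components 1 (21.3% of the variance) and 2 (19.8%) of log2 CPM over the 9694 tested transcripts, 1 point per library, animal ectoderm in blue and lateral ectoderm in orange. Lateral replicates 1 and 4 lie far from the other 6 libraries on component 2 and at opposite ends of component 1, and all 4 animal libraries lie above all 4 lateral ones on component 2.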

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

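In groups of 4 libraries, a value counted as far from the others when its gap to the nearest one, as a share of the group's range, exceeded Dixon's 95% critical value. This was met in 4 of 27 groups tested. Chance flags about 1 in 20 where values are continuous and normally distributed. ENSDART00000136415.3 and ENSDART00000057053.6 each stood at 0.399 CPM in animal replicate 2 and at 0 in the other animal libraries, a difference of 1 read. With the other values all equal, the gap is the whole range whatever its size. The rate of 1 in 20 therefore does not apply to these flags. ENSDART00000057053.6 stood at 33.9 CPM in lateral replicate 4, against 25.5 to 27.0 CPM in the other lateral libraries. ENSDART00000105286.5 stood at 5.18 CPM in animal replicate 2, against 20.9 to 23.4 CPM in the other animal libraries.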

How the results depend on the processing

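The added alternatives, chosen after seeing the data, were whole-number transcripts only, TPM, leaving out lateral libraries 1 and 4 together, and thinning; the others were fixed before the data were examined. The direction of every one of the 29 transcripts was kept under each alternative that tested it. As all 29 were completely separated and the alternatives used the same libraries or some of them, a reversal was hardly possible. The counts (29 in all, 20 higher in lateral, 9 higher in animal) stayed within 1.5 times under RLE and upper quartile scaling, the stricter filter, robust dispersions, length offsets, the surrogate variable, TPM (33) and thinning (31). Among the 3138 transcripts tested with whole numbers only they were 34, 25 and 9, where 16, 14 and 2 of the 29 had whole numbers. They were 90, 57 and 33 with DESeq2, which tested 12790 transcripts. With no filter on low counts, which tested 30850, they were 290, 177 and 113. All 29 were included in both. With limma voom 17 passed, 9 of them higher in lateral. At an adjusted p of 0.01 they were 15, 13 and 2, and against a 1.5-fold change 4 were higher in animal. Without lateral libraries 1 and 4 together they were 14, 9 and 5. Leaving out 1 library gave 18 (without animal replicate 3) to 24 in all. It gave 3 (without animal replicate 4) to 7 higher in animal, with 4 without animal replicate 1 or 3. In all 8 such fits 15 of the 29 passed, 13 of them higher in lateral. Of the 29, 13 were lost in at least as many of these fits as kept them, and 2 passed in none. With the replicate block the counts were 9, 8 and 1. Same-numbered libraries showed no shared deviation (correlations from -0.0299 to 0.0411, against -0.1195 to 0.1339 for other pairs). Of the 8 libraries, 0 correlated best with its own number. The labels do not say whether equal numbers mark paired samples, and so few correlations cannot exclude it. The cause of these changes in the counts was not tested. ENSDART00000057053.6 passed in all 24 alternatives, with adjusted p from 4.87e-21 to 0.0484. ENSDART00000136415.3 lost its call in 9 of 22, ENSDART00000105286.5 in 12 of 22 and ENSDART00000126097.4 in 10 of 23, with 0 reversals. The alternatives for gene lists and for mitochondrially encoded genes were not run, because transcripts were not matched to genes. In the simulated libraries 9.09% of the 2-fold changes that passed the filter were recovered, over all abundances together. The simulation gave more calls than the real data, so this rate can be too high for them.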

Other observations

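The tests of read division and those on variation among the lateral libraries were chosen after the results were seen, as were the exact binomial and rank-sum tests.

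The difference between the regions was not one that any grouping of the libraries gives. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave 29 or more transcripts. The highest of the others gave 4. As 1 in 35 is the smallest share this test can give, it argues against chance for the set but does not exclude it. The other splits also mix the regions within each group, which can raise the spread within groups and lower their calls. No difference in length was detected between the transcripts past the threshold and the tested ones, with medians of 1830 and 2001 nucleotides (permutation p = 0.591).

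More transcripts were higher in lateral than in animal ectoderm, 20 against 9, although an even division is not excluded (exact binomial p = 0.0614). Thinning every library to the smallest total left a median ratio of 2.41 over 20 draws, which argues against deeper animal libraries as its whole source, while with limma voom the numbers were 9 and 8. Scaling stays open, because RLE and upper quartile factors gave the same 29 transcripts (ratio 2.22) and so tested little, and so does read division: whole-number transcripts gave a ratio of 2.78, but 14 of the 20 and 2 of the 9 transcripts had whole numbers, and those with divided reads were 6 against 7. The changes were also larger in the lateral set (exact rank-sum p = 0.00167), but so were their standard errors (exact rank-sum p = 0.00969). A fold must be larger to pass where its error is larger. The binomial and rank-sum tests treat transcripts as independent. These transcripts come from the same 8 libraries and are not independent, so the p-values cannot be taken at face value. A difference in biology between the regions in this respect was not tested further.

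Lateral libraries resembled one another less than animal libraries did, by 0.0372 in mean correlation, but this difference did not pass its exact permutation test (p = 0.171). At equal read totals the difference was 0.028 (exact permutation p = 0.2), between 0.0275 and 0.0287 over 20 draws, which argues against lower read totals as the whole cause. Thinning matches read totals only, and 17231 against 16795 transcripts were then detected on average, so a difference in library complexity stays open. Without lateral replicate 1 the difference in correlation was 0.0145 at equal totals, and between 0.0223 and 0.0385 without any other lateral library. One library that stands apart and a wider spread of lateral ectoderm therefore cannot be told apart with 4 libraries.

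The 20 transcripts higher in lateral ectoderm deviated unequally among the lateral libraries. Their mean deviation from each transcript's lateral mean was -0.27, -0.34, 0.27 and 0.34 on the log2 scale in replicates 1 to 4 (SD over the transcripts 0.56, 0.33, 0.57 and 0.34), with 5, 2, 14 and 18 of the 20 above their own mean. The variance of this mean lay at percentile 98.96 of 10000 random sets of other transcripts of the same abundance, but those sets were not selected as the 20 were and the deviations had been seen first, so chance stays open. The median of all tested transcripts spanned 0.0332 of the range of the set, but TMM scaling holds that median near 0, so scaling of single libraries stays open. The transcripts higher in animal ectoderm had mean deviations of 0.00, 0.33, 0.24 and -0.57 in the same libraries, opposite in sign in replicates 2 and 4 but not in replicate 3. No biological explanation was tested.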
